A study of Mus musculus with 2 samples.

How the data were processed

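Total RNA of mouse embryonic stem (ES) cells was measured on dual-colour Agilent expression arrays, 1 array for the wild-type line V6.5 and 1 array for Utx knockout cells. Per the labels' protocols, the cells were kept undifferentiated on gelatin with leukaemia inhibitory factor (LIF). Differentiation was started by removing LIF and adding 100 nM retinoic acid (RA), and RNA was taken after 48 h with a kit from Qiagen. Per the labels' protocols, oligo-dT primed cRNA of the untreated cells carried Cy3 and that of the RA-treated cells of the same line carried Cy5. Each array therefore holds both conditions of 1 line, and the samples fall into 2 groups of 1 array. LIF withdrawal and RA came together, so no ratio separates their effects.

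The deposited values are taken as log2 ratios, 1 per feature and array, for 44397 features. Limma is named without version or role in the submitters' processing notes. The background correction and the within-array normalization are not given in the sources used here. Each deposited column has a mean of 0 within rounding, so the authors' values were centred on the mean of each array, and the column medians were -0.03 for V6.5 and -0.03 for the knockout. The log base was inferred from the values: the largest ratio of 5.86 is 58.3-fold as log2 and would be 732000-fold as log10. A natural log was not weighed, and every fold given rests on log2. The direction is RA-treated over untreated as a likely reading, from the dyes in the labels and from limma's convention of red over green. No dye swap was used here, so a bias of 1 dye at a gene has the same sign on both arrays and adds to its RA response. Spot intensities were not used here, so the signal over background behind each ratio is unknown, and the number of arrays limits the precision.

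Features were named through the platform annotation, in which 33026 had 1 gene symbol, 0 had several and 11371 had none here. The unnamed features entered only the counts over probes. Of the 22485 genes, 21964 had an Entrez number in the RefSeq table of assembly GRCm38.p6, and 0 of them had another symbol there. That table served for names alone. No genome build is named in the sources used here and no coordinates are given. The features of a gene were averaged on each array. This concerned 6138 genes with 2 or more features, of which 387 had 10 or more, and 16347 genes rested on 1 feature.

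The RA response of each line was described by the log2 ratio per gene and by counts of genes past 2-fold in each direction, with no test, since 1 array per line gives no replicate check. The difference between the lines was the knockout ratio minus the V6.5 ratio, again with no test. Pearson and Spearman correlations and an orthogonal slope were computed across genes, which are not independent replicates, with 1000 bootstrap draws of genes for a 95% interval. The RA response shared by the 2 lines was tested with limma 3.58.1 in R 4.3.3, fitting an intercept over both log2 ratios with lmFit and eBayes. The test was two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. This fit takes the 2 lines as 2 samples of the same response and has 1 residual degree of freedom plus 2.98 prior degrees of freedom. Any difference between the lines goes into its residual. Its p-values and SEs rest on the spread between these 2 arrays, which eBayes draws toward a value common to all genes. They say nothing of the spread between replicate cultures. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the remaining steps.

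The limma step was tested on simulated data with 22485 genes. It recovered 0 of 50 genes changed by a log2 ratio of 1, 36 of 50 changed by 2, 40 of 50 changed by 3 and 39 of 50 changed by 4, with 0 false calls. The simulation changed far fewer genes than the 2009 up and 1784 down called in the data, and held no dye bias. Its rates of recovery and of false calls therefore do not describe the calls in the data. The percentile step was checked on random lists drawn from the V6.5 ratios, some with their median shifted by 1. This checks the computation only.

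The 32 gene lists, the limma test, the settings to be varied and the rule for naming genes were fixed before the data were examined. For each list, the median ratio on each array and the median difference were placed among 10000 random gene lists of the same size. These percentiles describe these arrays and are not p-values, and the random lists were not matched on expression because only ratios were used. Random lists matched on mean ratio took, for each RA pathway gene, 1 of the 20 genes closest in mean outside the RA pathway and Hox lists. These matched lists and the other tests of explanations were chosen after the values were seen. The Klk1 family and the other families were also grouped by symbol after their values were seen. The RA pathway list shares Hoxb1 with the Hox lists, Stra8 with the germline list and Cdx1 with the Wnt list. The LIF-STAT3 list shares Klf4 and Tfcp2l1 with the pluripotency list, and some other lists share members too. Every Hox gene is in both a cluster list and a paralog list. Named genes were the 8 highest and 8 lowest on each array, the 10 most positive and 10 most negative differences, and the 6 with the lowest p in each direction of the shared fit. In every list, the 2 members with the largest absolute mean and the 2 with the largest absolute difference were added. Kdm6a, Kdm6b, Uty and every Hox gene past 2-fold on either array were always named. Genes with placeholder names were counted but not ranked, and a gene with several features was ranked only where all its features had the same sign. List members named outside this rule, because 5 or fewer members passed or because they illustrate a list, were chosen after their values were seen. They comprise Rarb, Cyp26b1, Tgm2, Meis1, Meis2, Pou5f1, Nanog, Sox2, Esrrb, Nodal, Tex19.1, Tcl1, Stat3, Lifr, Junb, Hoxa4, Hoxa10, Hoxc13, Hoxd9, Tcstv1, Col1a1, Col1a2, Col3a1, Rbp4, Lama1, Sparc, Thbd, Esx1, Tead4, Isl1, Wnt3, Tbx6, Otx2, Sox3, Neurog2, Zic1, Stmn2, Cbx2, Phc2, Kdm2b, Phc1, Pcgf2, Cdkn1c, Cdk2, Mdm2, Dlk1, Ndn, Meg3, Id1, Id4, Msx2, Smad7, Nkd1, Dkk1, Wnt8a, Znrf3, Notch3, Slc2a3, Hk2, Pfkp, Pdk1, Hspa8, Gadd45b, H2-D1, Psmb9, Tap1, Gbx2, Ezh1, Hoxa11, Zfp352 and Eif1a.

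Other settings tried were thresholds of 1.5-fold and 3-fold, centring on the median, scaling the knockout array to the V6.5 spread, quantile normalization, and the median or the largest probe of a gene in place of the mean. Further ones were genes with 2 or more probes of 1 sign, probes in place of genes, robust eBayes, limma's treat against 1.5-fold, and random lists matched on the number of probes, all fixed before the data were examined. Leaving out genes with placeholder names and the Zscan4, Pramel, Usp17l, Tdpoz and Tcstv families was added after seeing the data.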

Results

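The RA response of mouse ES cells was measured with and without Utx. Utx, encoded by the X-linked gene Kdm6a, is a histone demethylase that removes the repressive H3K27me3 mark. V6.5 is a wild-type mouse ES cell line, and the other line was a Utx knockout. LIF, the cytokine that holds mouse ES cells undifferentiated, was withdrawn and 100 nM RA, a morphogen that drives ES cells out of pluripotency, was added for 48 h. Both changes came together, so LIF withdrawal and RA cannot be told apart. Below, the RA response and changes after or with RA stand for both. RNA of untreated and RA-treated cells of 1 line shared an array, 1 array per line. Each of 22485 named genes thus has 2 values, the log2 ratio of RA-treated over untreated RNA in V6.5 and in the knockout. There are no replicates, so no value of a single line and no difference between lines has a replicate check. Within an array, the SD between features of a gene with 2 to 9 features had a median of 0.14 (log2) on both arrays. Single genes with large ratios lay on either side of it. In V6.5 and the knockout it was 0.60 and 1.15 for Hoxb3 and 0.73 and 0.88 for Zscan4c, against 0.055 and 0.088 for Lrrc2. A log2 ratio above 0 is read as higher after RA, the likely direction from the dyes in the labels. The RA targets Cyp26a1 (3.54 and 4.27) and Rarb (2.38 and 2.40) had positive ratios on both arrays, which goes with this reading.

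The probe of Kdm6a had a ratio of -0.39 in V6.5 and -0.16 in the knockout. This ratio compares 2 conditions within a line, so it does not check the knockout. Kdm6b, the related H3K27 demethylase, had ratios of 0.07 and -0.13, and Uty, the Y-linked relative of Utx, had 0.03 and -0.14. None of these genes passed the limma test of the shared response, with adjusted p of 0.129 for Kdm6a, 0.849 for Kdm6b and 0.672 for Uty.

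The V6.5 array shows how wild-type cells responded to RA. Leaving aside placeholder names, the highest genes were those of the Zscan4 family, which marks a transient state resembling the 2-cell embryo. Zscan4c was 28.2-fold higher after RA, Zscan4f 27.2-fold, Zscan4-ps3 26.6-fold and Zscan4e 24.3-fold. Pramel39 was 22.5-fold and Pramel20 21.1-fold higher, and Pramel28, of the same gene family expressed in early embryos and germ cells, had a log2 ratio of 4.46. Hoxb2, a patterning gene of the hindbrain, was 21.9-fold higher. At the other end stood members of the Klk1 family of kallikrein proteases, in which 6 of 14 genes were at least 2-fold lower and the median was -0.11, with log2 ratios of -3.71 for Klk1b5, -3.69 for Egfbp2, -2.69 for Klk1 and -2.45 for Klk1b8. Ly6g6e (-3.67), Glod5 (-3.66), Lrrc2 (-2.54) and Pla2g7 (-2.42) completed the lowest genes. In all, 566 genes were at least 2-fold higher and 358 at least 2-fold lower, which is 4.11% of the genes measured. Of the 156 genes past 2-fold with several features, 152 had all features of 1 sign. The Zscan4, Pramel and kallikrein genes have near-identical copies whose probes can share signal, so the value of a single copy is uncertain.

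On the knockout array the same families stood at the top. Zscan4f was 51.6-fold higher after RA, Zscan4e 42.6-fold, Pramel39 33.1-fold, Zscan4c 33.0-fold and Pramel28 32.6-fold. Hoxb2 was 31.3-fold and Stra8, an RA-induced gene needed for entry into meiosis, 30.1-fold higher. Zscan4-ps3 was 29.2-fold higher. The lowest ratios were those of Ly6g6e (-3.54) and Glod5 (-3.35). Foxd3, a transcription factor of pluripotent and neural crest cells, had -2.91, Slco4a1 -2.88, Lrrc2 -2.75, Ccn5 -2.67, S100a4 -2.63 and the neuronal factor Neurod1 -2.59. On this array 656 genes were at least 2-fold higher and 371 at least 2-fold lower, 4.57% of the genes. Of 182 genes past 2-fold with several features, 177 had all features of 1 sign.

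The shared fit asks which genes moved with RA in both lines. The Zscan4 genes, a run of Hox genes and the RA-degrading enzymes Cyp26a1 and Cyp26b1 rose. Of 15 LIF targets 6 fell, as did 9 of 30 pluripotency genes, with 2 shared genes in both counts, and 10 of 18 fibroblast genes. Whether RA or the withdrawal of LIF moved them cannot be told apart. Values after ± are limma's moderated SEs (n = 2 arrays), drawn toward a value common to all genes, and not the spread of a gene's own 2 ratios. Among the genes with the lowest p, Zscan4c had a mean log2 ratio of 4.93 ± 0.09, Zscan4-ps3 4.80 ± 0.08, Pramel20 4.46 ± 0.08 and the deubiquitinase pseudogene Usp17le-ps 4.19 ± 0.08. Foxa1, a pioneer factor of endoderm, rose by 3.11 ± 0.07 and Hoxb1 by 3.09 ± 0.07. Glod5 fell on both arrays (-3.66 and -3.35), Ly6g6e fell to -3.61 ± 0.08, Lrrc2 to -2.64 ± 0.09, the G protein subunit Gna14 to -2.22 ± 0.07, Ly6g6d to -2.19 ± 0.08 and the collagen crosslinking enzyme Lox to -2.08 ± 0.08. In limma with eBayes, 2009 genes rose and 1784 fell at a Benjamini-Hochberg adjusted p under 0.05, with a smallest adjusted p of 0.00381. A mean of at least 2-fold was reached by 509 of those that rose and 295 of those that fell, while 1628 of all genes that passed had a mean under 1.5-fold. Tested against 1.5-fold with treat, 196 genes rose and 97 fell. A dye bias at a gene is alike on both arrays and is part of these values.

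Of 23 measured RA pathway genes, 14 rose and 1 fell, and 16 rose and 2 fell when adjusted over the list alone. Stra8 rose by 4.64 ± 0.15, and Cyp26a1, the enzyme that degrades RA, by 3.91 ± 0.20. The receptor Rarb had ratios of 2.38 in V6.5 and 2.40 in the knockout. The member that fell was the transglutaminase Tgm2, with -1.24 and -2.33. Crabp2, a carrier protein for RA, had 0.67 and 2.65 and Nr2f2, an orphan nuclear receptor, 0.20 and 2.17; neither passed (adjusted p of 0.104 and 0.191 in limma). The list median was 0.99 in V6.5 and 2.13 in the knockout, above those of all 10000 random lists on both arrays.

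Hox genes, which pattern the body axis, rose in all 4 clusters. Of 14 measured genes of paralogs 1 to 5, 11 rose and 0 fell, and 13 rose when adjusted over the list alone. The members that did not pass in limma were Hoxa2, with 1.12 and 2.72 (adjusted p of 0.0525), Hoxc5, with 0.53 and 1.83, and Hoxd3, with 0.14 and 0.73. Of 24 genes of paralogs 6 to 13, 9 rose and 1 fell, with 9 and 2 over the list alone. By cluster, 9 of 10 HoxB genes rose (9 also over the list alone), led by Hoxb2 at 4.71 ± 0.15, Hoxb4 at 3.61 ± 0.12 and Hoxb5 at 3.34 ± 0.21. Among the others, Hoxb8 rose by 2.46 ± 0.41, Hoxb6 by 2.42 ± 0.28, Hoxb7 by 2.16 ± 0.14 and Hoxb9 by 1.33 ± 0.17, and Hoxb3 had 1.59 and 2.41. In HoxA, 5 of 10 rose, and over the list alone 6 rose and Hoxa11 fell: Hoxa3 by 3.81 ± 0.10, Hoxa5 by 2.84 ± 0.28, Hoxa7 by 1.56 ± 0.10, and also Hoxa4 and Hoxa10. In HoxC, Hoxc4 rose by 2.73 ± 0.47 and Hoxc9 by 1.89 ± 0.39, and Hoxc13 fell to a mean of -0.76, 2 up and 1 down of 9 members by either adjustment. In HoxD, 4 of 9 rose by either adjustment: Hoxd4 by 1.26 ± 0.23, Hoxd8 by 1.19 ± 0.07, Hoxd1 by 1.07 ± 0.13, and Hoxd9. The call of Hoxc9 was lost with robust eBayes, and Hoxa2 passed with 3 of the alternative settings. Cluster medians in V6.5 and in the knockout were 0.55 and 0.79 for HoxA, 1.90 and 3.02 for HoxB, 0.06 and 0.13 for HoxC and 0.64 and 0.51 for HoxD.

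**Figure D1:**
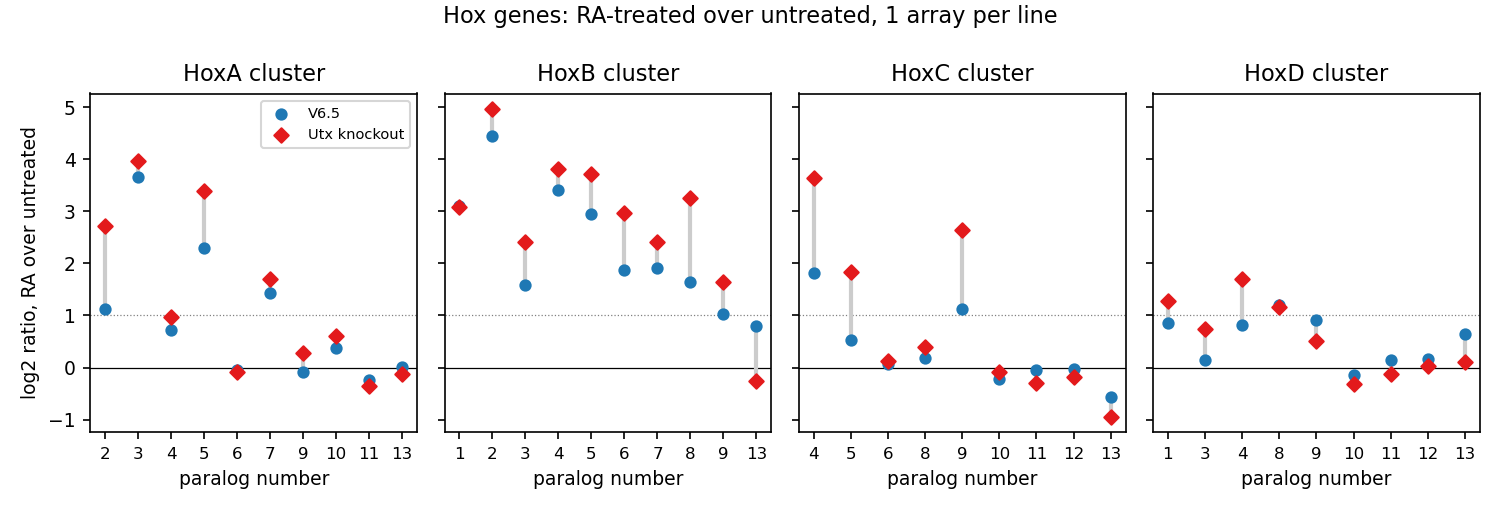
Log2 ratio of RA-treated over untreated RNA (vertical axis) for each measured Hox gene by paralog number (horizontal axis), 1 panel per cluster, with V6.5 as circles and the Utx knockout as diamonds; a grey bar joins the 2 arrays and the dotted line marks 2-fold. In HoxB, paralogs 1 to 9 lie between 1.03 and 4.45 in V6.5 and between 1.63 and 4.97 in the knockout, while paralogs 10 to 13 of HoxA, HoxC and HoxD stay under 2-fold on both arrays.

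Of 13 measured genes of the 2-cell-like state, 8 rose and 0 fell, and over the list alone 10 rose and 2 fell, Zfp352 and Eif1a. Zscan4f rose by 5.23 ± 0.24 and Gm4340 by 5.48 ± 0.21, the highest mean of the list. Tcstv3 (2.88 and 1.71) and Tcstv1 (2.86 and 2.25) also rose, while Pramel6 (1.80 and 0.58, adjusted p of 0.0802 in limma) did not pass. Of 20 germline genes, 8 rose and 0 fell, and 11 rose over the list alone. Besides Stra8, the meiotic cohesin Rec8 rose by 1.84 ± 0.09 and Dazl, an RNA-binding protein of germ cells, by 1.17 ± 0.24, a call lost with robust eBayes. Mael, of the piRNA pathway, had 0.59 and 2.02 without passing. Of 9 genes of MHC class I presentation, 6 rose, and 7 over the list alone. The immunoproteasome subunit Psmb8 rose by 3.19 ± 0.18, H2-K1 by 1.75 ± 0.14 over 11 features and the peptide transporter Tap2 by 1.68 ± 0.24, with Psmb9, H2-D1 and Tap1 also higher.

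The pluripotency network moved both ways. Of 30 measured genes, 9 fell and 3 rose, and 16 fell and 4 rose over the list alone. Klf4 fell to -2.05 ± 0.21, and Pou5f1 had -0.94 in V6.5 and -1.58 in the knockout and passed, as did Tcl1 (-1.38 and -1.43). Lefty1, a Nodal antagonist, rose by 2.26 ± 0.07, and the other members that rose were Nodal (0.71 and 0.53) and Tex19.1 (0.40 and 0.41). Nanog (0.29 and -0.16), Sox2 (-0.52 and -0.32) and Esrrb (-0.61 and -0.28) did not pass. Fgf4 and Tdgf1, with -0.64 and -2.07 and with -0.68 and -2.15, did not pass either (adjusted p of 0.0825 and 0.0806 in limma). Of 15 LIF-STAT3 response genes, 6 fell and 0 rose, with 11 down and 0 up over the list alone and 1 up, Gbx2, at an unadjusted p under 0.05. Socs3, the feedback inhibitor of this pathway, fell to -1.36 ± 0.09, and Stat3, Lifr and Junb fell as well. Osmr (-0.60 and -1.75) and Fos (-0.26 and -1.70) did not pass. List medians were -0.46 in V6.5 and -0.30 in the knockout for pluripotency and -0.51 and -0.75 for LIF-STAT3.

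Each lineage list held members that rose and members that fell, except the fibroblast list. Of 31 neural genes 4 rose and 8 fell (6 and 8 over the list alone). Irx3 rose by 2.25 ± 0.31, along with Sox3, Neurog2 and Zic1, while Neurod1 fell to -2.45 ± 0.10 and Otx2 and Stmn2 fell as well. Of 23 primitive streak and mesoderm genes, 3 rose and 1 fell (7 and 3 over the list alone): Nkx2-5 by 0.59 ± 0.10, Isl1, Wnt3, and, falling, Tbx6. Tal1 (-0.50 and -1.30) and Hand2 (0.72 and 0.28) did not pass. Of 27 endoderm genes, 2 rose and 3 fell by either adjustment: Foxa1 and the retinol carrier Rbp4 rose, and Lama1, Sparc and Thbd fell. Of 18 trophoblast genes, 3 rose and 1 fell (5 and 1 over the list alone): Gata3 by 2.56 ± 0.22, Tfap2c by 0.97 ± 0.09 and Esx1 rose, and Tead4 fell. Ascl2 (-1.02 and -0.19) and Krt7 (-0.57 and 0.40) did not pass. Of 18 fibroblast genes, listed because fibroblast feeders are used in ES cell culture, 10 fell and 0 rose, 11 and 0 over the list alone and at an unadjusted p under 0.05. S100a4 fell to -2.29 ± 0.19 and Thy1 to -1.13 ± 0.18. The collagens Col1a1 (-1.24 and -1.36), Col1a2 (-1.25 and -1.69) and Col3a1 (-1.35 and -1.32) fell too. The list median was -0.76 in V6.5 and -0.95 in the knockout.

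**Figure D2:**
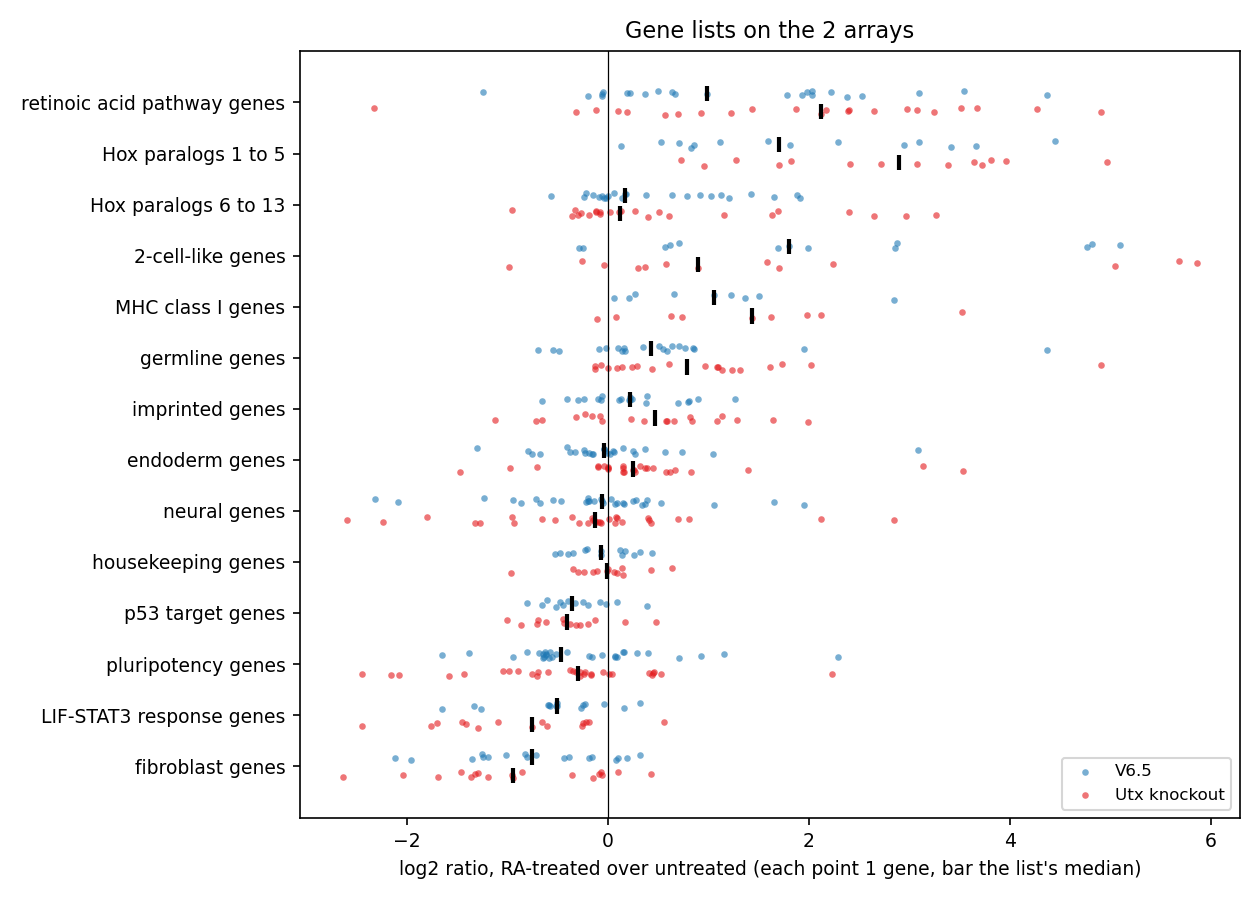
Log2 ratio of RA-treated over untreated RNA (horizontal axis) of each member of 14 gene lists (vertical axis), with V6.5 in blue and the Utx knockout in red, 1 array each; black bars mark list medians. The RA pathway medians lie at 0.99 and 2.13, those of the 2-cell-like genes at 1.80 and 0.90, and those of the fibroblast genes at -0.76 and -0.95.

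Of 14 H3K27 methyltransferase and demethylase genes, 1 fell and 0 rose, and 0 passed over the list alone, with 4 down (Eed, Phf1, Kdm6a and Ezh1) and 0 up at an unadjusted p under 0.05 in limma. The gene that fell was the Polycomb core subunit Eed, at -0.43 ± 0.07. Phf1 (-0.32 and -0.53), Rbbp7 (-0.23 and 0.12) and Phf19 (-0.97 and 0.81) did not pass. Of 18 PRC1 genes, 5 rose and 2 fell (6 and 4 over the list alone): Yaf2 by 0.89 ± 0.10, Bmi1 by 0.88 ± 0.16, Cbx2, Phc2 and Kdm2b rose, Phc1 and Pcgf2 fell, and Rybp (0.29 and -0.07) did not pass. Of 12 MLL complex genes, which include partners of Utx, 1 rose and 1 fell by either adjustment: Pagr1a by 0.42 ± 0.08 and Dpy30 to -0.69 ± 0.07. Kmt2a (0.02 and -0.23) and Kmt2b (0.13 and -0.09) did not pass. Of 12 DNA methylation genes, 1 rose and 2 fell (2 and 5 over the list alone). Mbd2 rose by 0.69 ± 0.08, while the methylcytosine dioxygenases Tet1 and Tet2 fell to -1.07 ± 0.09 and -0.66 ± 0.11, and Dnmt3l (-0.97 and -0.36) did not pass. Of 20 imprinted genes, 4 rose and 1 fell (6 and 3 over the list alone): Peg10 by 1.22 ± 0.22, Dlk1, Ndn and Cdkn1c rose and Meg3 fell. Of 6 Y-linked genes and 6 X-inactivation genes, 0 passed by either adjustment in limma. At an unadjusted p under 0.05, 1 Y-linked gene was lower, Eif2s3y, and 1 X-inactivation gene higher, Jpx. Eif2s3y had -0.19 and -0.83, Kdm5d 0.15 and 0.01, Jpx 0.23 and 0.24, Rlim 0.12 and 0.28, and Ftx -0.27 and 0.03.

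Targets of developmental signals moved both ways. Of 14 BMP and TGF-beta response genes, 8 rose and 2 fell (9 and 2 over the list alone). Id2, an inhibitor of differentiation factors, rose by 1.77 ± 0.10 and Id3 by 1.12 ± 0.20, along with Id1 and Msx2, while Id4 and Smad7 fell. Of 13 Wnt response genes, 4 rose and 2 fell by either adjustment: Cdx1 by 1.58 ± 0.19, Wnt8a, Dkk1 and Nkd1 rose, and Znrf3 and Ccnd1 fell. Of 14 Notch response genes, 1 rose and 6 fell (1 and 7 over the list alone). The ligand Jag1 fell to -1.30 ± 0.14, Hes6 to -0.93 ± 0.10 and Hes3 to -0.74 ± 0.15, the last lost with robust eBayes. Notch3 rose, and Dll1 (-0.71 and 0.04 over 10 features) did not pass. Of 24 cell cycle genes, 2 rose and 3 fell (2 and 4 over the list alone). The cyclin Ccnd2 rose (1.03 and 1.97) while Ccnd1 fell to -1.37 ± 0.18, Cdkn1c rose, and Cdkn1a and Cdk2 fell. Cdkn2b (0.01 and -0.66) did not pass. Of 14 p53 target genes, 1 rose and 8 fell (1 and 10 over the list alone), with Bbc3 at -0.74 ± 0.08, Fas at -0.74 ± 0.15 and Cdkn1a at -0.69 ± 0.11 over 11 features. The fall of Fas was lost with robust eBayes. Mdm2 was the member that rose. Of 19 glycolysis and hypoxia genes, 1 rose and 5 fell (3 and 6 over the list alone). The genes that fell were Ndrg1 at -1.46 ± 0.27, Hk1 at -1.05 ± 0.14, Hk2, Pfkp and Pdk1. Slc2a3 rose, and Slc2a1 (0.56 and 1.27) had an adjusted p of 0.0523 in limma. Of 16 heat shock and stress genes, 1 rose and 3 fell (1 and 4 over the list alone): Ddit3 fell (-0.90 and -1.10), Chac1 fell to -0.88 ± 0.13, Gadd45b fell and Hspa8 rose. Hspa1a (1.12 and 0.16) and Gadd45a (0.31 and 1.03) did not pass. Of 14 housekeeping genes, 1 rose and 1 fell (2 and 4 over the list alone): Gusb by 0.54 ± 0.09 and Tfrc to -0.74 ± 0.13, both over at least 10 features, while Pgk1 had -0.21 and -0.00.

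Fewer list members passed against 1.5-fold with treat. In this test 7 RA pathway genes rose and 0 fell, as did 5 Hox genes of paralogs 1 to 5 and 3 of paralogs 6 to 13. By cluster, 2 HoxA, 5 HoxB, 0 HoxC and 1 HoxD genes rose and 0 fell. Among 2-cell-like genes 5 rose, among germline genes 2 and among MHC class I genes 3, with 0 down in each. Of the pluripotency genes 1 rose and 1 fell, of LIF-STAT3 genes 0 and 2, of neural genes 1 and 3, of endoderm genes 1 and 1, of trophoblast genes 1 and 0, of fibroblast genes 0 and 5, and of BMP and TGF-beta genes 2 and 1. In each other list 0 genes passed treat: mesoderm, the 4 chromatin lists, imprinted, Y-linked, X-inactivation, Wnt, Notch, cell cycle, p53, glycolysis, stress and housekeeping. Their counts without the 1.5-fold bound are given above.

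The design sets the RA response of the knockout against that of V6.5, which asks whether the response differs without Utx. At the gene level, 131 genes had a knockout ratio at least 2-fold above the V6.5 ratio and 105 at least 2-fold below it, 1.05% of the genes. The largest positive difference was that of Lrp2, the endocytic receptor megalin, with 1.05 in V6.5 and 3.53 in the knockout. Zbtb16 (-0.05 and 2.24), Meox1 (0.20 and 2.36), Crabp2, Nr2f2, Gprc5c (0.80 and 2.76) and Hoxc4 (1.81 and 3.64) also had a knockout ratio at least 3.56-fold above the V6.5 ratio. The desmosome gene Dsp had -0.20 and 1.79 over 11 features, Prl4a1 -0.89 and 1.52, and Ltb -1.63 and 0.59. The largest negative differences were those of the defensin Defb25 (2.75 and 0.64) and the lectin Clec10a (3.14 and 1.08). They were followed by Cidea (1.18 and -0.70), the Wnt target Sp5 (0.38 and -1.46), Fgf7 (0.77 and -1.03), Iqcf1 (2.44 and 0.67), Nmnat3 (-0.62 and -2.32), Ccn5 (-1.01 and -2.67), Trim67 (1.62 and -0.01) and Pramel17 (2.69 and 1.09). These differences were not tested, because each line has 1 array, and they hold culture and array along with genotype. No array sets knockout RNA against V6.5 RNA. A larger ratio can therefore come from a lower level in untreated cells or a higher one after RA. Of the 45 genes past 2-fold in the difference with several features, 45 had all features of 1 sign.

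At least 2-fold on both arrays stood 381 genes higher and 214 lower, against 16.5 and 5.9 for independent lists of the same sizes, and 0 genes were 2-fold higher on 1 array and 2-fold lower on the other. Past 2-fold on 1 array alone were 185 higher and 144 lower genes in V6.5 and 275 and 157 in the knockout. Across genes, Pearson's r was 0.837 (95% bootstrap interval 0.828 to 0.846) and Spearman's rho 0.733. The orthogonal slope of knockout on V6.5 was 1.05 (1.03 to 1.07). Genes are not independent replicates, so these intervals cover sampling of genes only. A dye bias at a gene has the same sign on both arrays, so it can add to these overlaps and correlations. How much of them it makes up was not tested.

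**Figure D3:**
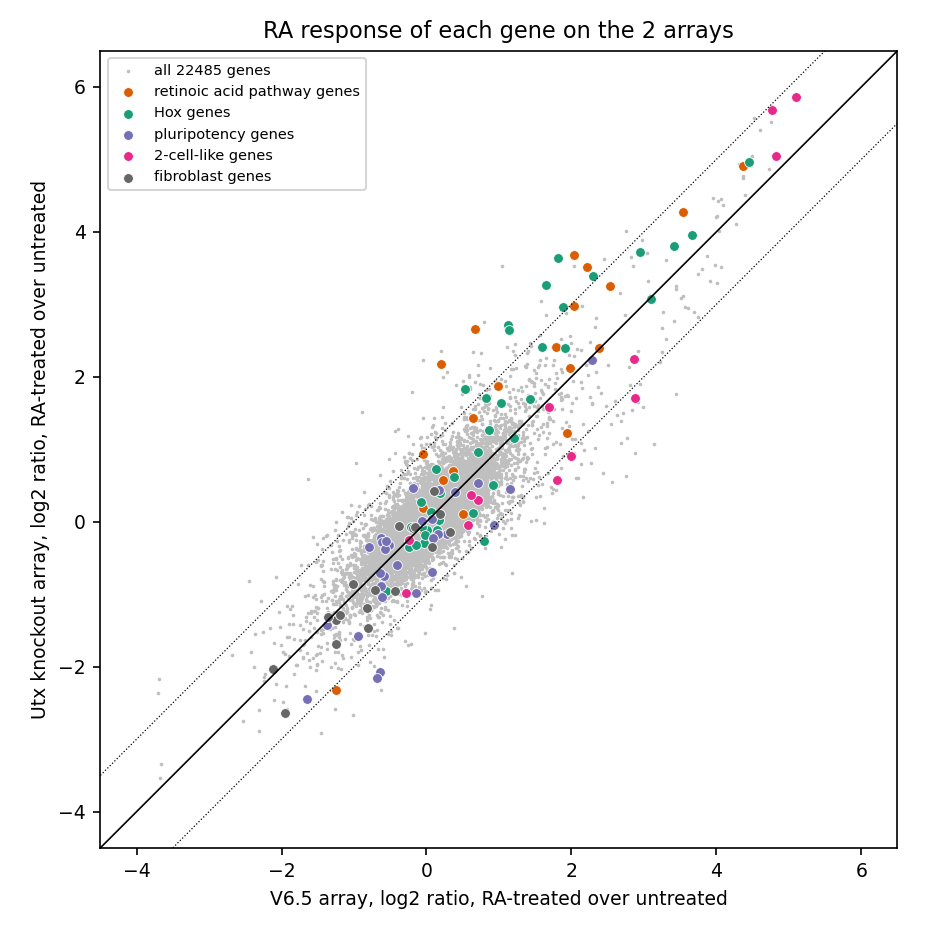
Log2 ratio of RA-treated over untreated RNA in V6.5 (horizontal axis) against the Utx knockout (vertical axis), 1 point per gene, with members of 5 gene groups in colour; the solid line marks equal ratios and the dotted lines a 2-fold difference. The genes follow the diagonal with a Pearson's r of 0.837, to which a dye bias alike on both arrays can add. Above the dotted lines lie 131 genes and below them 105.

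Among the gene lists, RA pathway and early Hox genes had higher ratios on the knockout array. In the RA pathway list 17 of 23 members were higher there, with a median difference of 0.54, and in Hox paralogs 1 to 5 it was 13 of 14, with a median of 0.69. The largest differences among Hox genes after Hoxc4 were those of Hoxb8 (1.61), Hoxa2 (1.60), Hoxc9 (1.52), Hoxc5 (1.30), Hoxa5 (1.10) and Hoxb6 (1.08). Quantile normalization lowered the RA pathway median to 0.33. Germline genes were higher in 16 of 20 (median 0.39), endoderm genes in 22 of 27 (0.24) and MHC class I genes in 6 of 9 (0.38). The 2-cell-like genes went the other way, lower in 10 of 13 (median -0.41), with -1.23 for Pramel6 and -1.17 for Tcstv3. The 3 members with the highest means were higher there, Zscan4f by 0.92, Gm4340 by 0.76 and Zscan4c by 0.23, the last turning below 0 with quantile normalization. Each of these medians except that of the 2-cell-like genes lay above all 10000 random lists, and that of the 2-cell-like genes lay below all. LIF-STAT3 genes were lower in 12 of 15 (median -0.19), with -1.44 for Fos over 10 features and -1.16 for Osmr, and pluripotency genes in 20 of 30 (median -0.17). The imprinted gene Mest, with 12 features and a ratio of 0.22 in V6.5, differed by 1.77, and H19 by -1.09, with an SD of 1.51 between its 2 features. The imprinted list itself had a median difference of 0.10, which turned to -0.045 with the largest probe of each gene.

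Among the other lists, median differences were 0.26 for HoxA, 0.56 for HoxB, 0.14 for HoxC and -0.15 for HoxD, whose mean difference was 0.04, and -0.03 for Hox paralogs 6 to 13, whose mean was 0.12. They were -0.09 for neural, -0.01 for primitive streak and mesoderm, 0.16 for trophoblast and -0.11 for fibroblast genes. Among chromatin lists they were -0.07 for H3K27 enzymes, with a mean of 0.09, 0.04 for PRC1, -0.11 for the MLL complex and -0.11 for DNA methylation. Signalling and metabolic lists had -0.06 for BMP and TGF-beta, -0.05 for Wnt, -0.01 for Notch, with a mean of 0.01, -0.09 for p53 targets, -0.08 for glycolysis and hypoxia and -0.18 for heat shock and stress. Cell cycle genes had 0.01, with a mean of -0.02, housekeeping genes 0.03, Y-linked genes -0.16 and X-inactivation genes 0.06. Single genes with larger differences were Irx3 (1.19) and Zic2 (-1.05) among neural genes, Hnf4a (0.83) in endoderm, Krt7 (0.97) and Ascl2 (0.83) in trophoblast, Ccnd2 (0.94) in the cell cycle and Ndrg1 (-1.03) in hypoxia.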

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

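No explanation was tested for the genes in this part, and they were picked by a size rule applied after the values were seen. In 5 named genes the ratios of the 2 lines lay at least 1.5-fold from 0 on opposite sides, and none of these differences was tested, since each line has 1 array. Prl4a1, of the placental prolactin family, had a log2 ratio of -0.89 in V6.5 and 1.52 in the knockout, a difference of 2.41. Ltb, a cytokine of the tumour necrosis factor family, had -1.63 and 0.59, a difference of 2.21. Phf19, a Polycomb accessory protein that binds methylated histone H3, had -0.97 and 0.81, a difference of 1.78. The difference ran the other way for Cidea, a lipid droplet protein, with 1.18 and -0.70 and a difference of -1.88, and for the growth factor Fgf7, with 0.77 and -1.03 and a difference of -1.80. Each of these genes rests on 1 feature per array, so no agreement between probes could be checked.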

How the results depend on the processing

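Leaving out placeholder names and the 2-cell gene families was chosen after seeing the data, and the other settings were fixed before. At a 1.5-fold threshold, 1504 genes were higher and 1205 lower in V6.5, 1637 and 1138 in the knockout, 562 and 422 in the difference, and 1045 and 725 on both arrays. At 3-fold, the counts were 213 and 75, 268 and 100, 20 and 15, and 146 and 45 in the same order. With only genes of 2 or more probes of 1 sign they were 87 and 65, 104 and 73, 23 and 22, and 54 and 39, from 6138 genes. Over probes in place of genes they were 1174 and 689, 1305 and 815, 255 and 239, and 812 and 417, from 44397 features. The counts at other thresholds follow from the threshold, and the cause of the others was not tested. Limma's treat against 1.5-fold left 196 genes higher and 97 lower. The slope across genes was 1.02 with the knockout array scaled, 1.03 with quantile normalization and 1.01 over probes. Without placeholder names and the families together, the slope was 1.09 and r was 0.821. The cause was not tested.

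Of the list medians, 472 of the recomputed values moved by less than the SD between probes and 8 by more. With the largest probe of each gene, the RA pathway median was 1.17 in V6.5, the HoxB median 3.24 in the knockout, that of Hox paralogs 1 to 5 was 1.91 in V6.5 and 3.29 in the knockout, and that of the 2-cell-like genes 1.99 in V6.5. With the same choice the imprinted median difference turned to -0.045. With quantile normalization, the RA pathway median difference was 0.33 and the knockout median of Hox paralogs 1 to 5 was 3.04. The cause was not tested. The shared responses of the 141 named genes were counted once per gene under each alternative setting of the fit. Of these pairs of gene and setting, 782 kept their side of the threshold, 50 lost it and 14 gained it. Among genes that passed in the main fit there were 0 changes of direction, and the sign of the others was not followed. Of those lost, 46 were under treat and 4 under robust eBayes (Dazl, Fas, Hes3 and Hoxc9). Limma called 2493 genes up and 1762 down with array medians at 0, 2257 and 2081 with quantile normalization, 2012 and 1800 with the median of probes, 2520 and 2224 with the largest probe, and 1977 and 1753 with robust eBayes.

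No paired analysis was possible because each line has 1 array and the labels give no shared replicate numbers. Leaving out a line was not run, since 1 array leaves no residual degree of freedom and returns that array's own values. Reading the values as log10 was not run, because it would make the largest ratio 732000-fold, and a natural log was not weighed. Without intensities, signal over background sets no limit that can be stated here.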

Other observations

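The families in this part, and the tests of explanations, were chosen after the values were seen, whereas the limma test, the RA pathway and fibroblast lists and quantile normalization were fixed before. The H2-Q genes, nonclassical MHC class I genes, were also higher after LIF withdrawal with RA: 7 of 8 passed in limma, with medians of 1.58 in V6.5 and 1.51 in the knockout. Of the 8 H2-T genes, 3 rose and 1 fell in limma, with medians of 0.05 in V6.5 and 0.09 in the knockout. The Meis genes, homeobox partners of Hox proteins, had medians of 2.03 and 3.51, with 3 of 3 higher on the knockout array. Of the other families of the early embryo, Usp17l was lower on the knockout array in 6 of 6 members (median difference -0.85), Tdpoz in 7 of 7 (-0.41) and Obox in 7 of 8 (-0.44), while Pramel, the largest of them, was lower in 20 of 34 (-0.04). Linker histone H1 genes were lower there in 10 of 10 (median 0.44 in V6.5 and -0.08 in the knockout), H2B genes in 13 of 14 (0.64 and 0.27) and H4 genes in 8 of 9 (0.43 and -0.12). The directions of these medians between the lines held with centring, scaling and quantile normalization, whereas the median difference of the Zscan4 genes of 0.23 turned to -0.15 with quantile normalization. Copies within a family can share probes, so the members are not independent. The cRNA was oligo-dT primed, so histone transcripts without a poly(A) tail would not be primed as intended. The H2A and H3 histone genes were not summarised as families.

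The 387 genes with 10 or more features give the differences with the smallest probe error. Among them, 6 had a knockout ratio at least 2-fold above that of V6.5: Dsp (1.99), Mest (1.77), the gap junction gene Gja1 (1.39), the interferon-induced GTPase Igtp (1.36), Fbxo32 (1.13) and Tcim (1.04). It was at least 2-fold below in 4 genes, Fos (-1.44), Ctxn3 (-1.35), Olfr713 (-1.20) and Cpt1a, which had -1.32 in V6.5 and -2.32 in the knockout. The SD between features was 0.04 for Fos, 0.06 for Gja1, 0.08 for Igtp and 0.58 for Dsp. Features repeat the measurement on the same RNA and say nothing of another culture. Of the 11371 features without a symbol here, 264 were at least 2-fold higher and 101 at least 2-fold lower on both arrays.

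The RA pathway list had larger ratios on the knockout array, with 17 of 23 members higher and a median difference of 0.54. A wider scale of that array is argued against: random lists of other genes matched on mean ratio had 95% of their medians between -0.22 and 0.25, and with quantile normalization 74 of 10000 such lists reached the list's 0.33. A larger response of all RA-raised genes outside the Hox genes is argued against as the whole of this difference, but not as a part of it. The other 537 genes with a mean of at least 2-fold, with Hox genes left out, had a median difference of 0.15. Of these genes, 321 had a larger ratio on the knockout array. Of 10000 random lists of them, 10 reached the 0.73 of the 15 members past 2-fold. The 537 genes include members of the 2-cell families, some of which were lower on the knockout array. Both sets of random lists take genes as independent. What stays open is a scale that varies with spot intensity, and a difference between the cultures, such as how far each had differentiated, which 1 array per line leaves untested. That loss of Utx may strengthen the response of RA targets is equally untested.

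Members of the 2-cell families with a mean log2 ratio from 1 to 3 were lower on the knockout array in 11 of 11 genes, with a median difference of -1.11, while the 14 members above 3 had a median difference of 0.18. Compression of all mid-range ratios on that array is argued against, since the other 505 genes of that range had a median difference of 0.17 (95% bootstrap interval 0.13 to 0.22). Compression that varies with spot intensity stays open, because these genes were chosen by ratio alone. The bootstrap also takes genes as independent. The genes come from 3 families, Pramel (-1.23), Usp17l (-1.10) and Tcstv (-0.89), picked for the pattern, and without probe sequences probes shared between near-identical copies within families and separate changes of each copy cannot be told apart. A different share of 2-cell-like cells in the cultures may contribute and was not tested. The genotype stays open as well.

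In the fibroblast list 10 of 18 genes fell after RA, which may reflect fibroblast feeder cells carried over into the untreated cells. Of the members, 5 lay above -0.28 (2 probe SDs below 0) on both arrays and 11 below it on both. Whether the 5 have signal above background is unknown without intensities, so carried-over cells and a fall within the ES cells cannot be told apart. The abundant collagens had -1.24 and -1.36 (Col1a1), -1.25 and -1.69 (Col1a2) and -1.35 and -1.32 (Col3a1). The labels name gelatin and no feeder layer for the cultures, 0 of the 18 genes are in another list, and how many of them ES cells express is not shown by ratios.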
